A study of Homo sapiens with 12 samples.

How the data were processed

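Polysome profiling with RNA sequencing was done on H1299, a human non-small-cell lung cancer cell line. Cells were transfected with a mix of 2 siRNAs against EIF3G (siEIF3G) or with a control siRNA (siCtrl) and lysed 72 h later. Per the labels, 10% of each lysate was taken as input, and the rest was separated on a sucrose gradient of 10% to 50%, from which the polysomal fraction was collected. The 12 libraries form 4 groups of 3 replicates: siCtrl input, siEIF3G input, siCtrl polysomal and siEIF3G polysomal. The labels do not say whether the replicates of a group are separate cultures, so p-values measure the spread between these libraries only, which may be technical.

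The values are the deposited TPM (transcripts per 1000000 transcripts), which the authors computed per gene and library; per the submitters' processing notes RSEM 1.3.1 was used with the genome build GRCh38.p13. The aligner, the annotation and any filter are not given in the sources used here. Every library sums to 1000000 over the 16172 genes of the table, within 0.54, so the number of reads behind each value is unknown and no interval for counting error can be given. TPM are shares of a library. A change of all mRNAs alike, such as a lower total of mRNA on polysomes, leaves them as they are. The table holds 15857 symbols that match protein-coding genes of the RefSeq annotation. Of the fixed lists, mitochondrially encoded mRNAs, long non-coding RNAs and snoRNA host genes have no member in the table and were not analysed here.

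Values were tested as log2(TPM + 1). Genes with a mean of at least 1 TPM over the 12 libraries were kept, which left 10605 genes and set aside 5567, among them 11 at 0 in every library. A linear model with 4 group means was fitted with limma 3.58.1 in R 4.3.3, with the mean-variance trend and moderated standard errors (8 residual degrees of freedom), and p-values were adjusted by Benjamini-Hochberg over the genes of each comparison, with a threshold of 0.05. The log scale with a pseudocount of 1 understates the fold change of genes with low values. Values stayed as deposited, with no rescaling between libraries.

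There were 5 comparisons: siEIF3G against siCtrl in input RNA, the same in polysomal RNA, the difference between these effects (polysome loading, the interaction of siRNA and fraction), and polysomal against input RNA within control cells and within knockdown cells. The 31 gene lists comprise 27 with at least 5 tested members, which were tested in each comparison with limma's camera at a preset correlation between genes of 0.01, adjusted over the lists. The 27 lists are: other eIF3 subunits, other translation initiation factors, elongation factors, cytosolic ribosomal proteins, nuclear-encoded OXPHOS (oxidative phosphorylation) subunits, mitochondrial ribosomal proteins, targets of ATF4 and the integrated stress response, endoplasmic reticulum chaperones, heat shock proteins (with the mitochondrial HSPD1 and HSPE1), cholesterol biosynthesis, DNA replication, mitosis, pro-apoptotic and anti-apoptotic genes, p53 targets, interferon-stimulated genes, inflammatory cytokines, immediate early genes, autophagy, lysosome, the mTOR pathway, epithelial and mesenchymal markers, proteasome, ribosome biogenesis, histones and housekeeping genes. Markers of other cell types had 3 tested members, too few for the list test. Camera asks whether the genes of a list differ from the other genes. It was repeated with a correlation estimated for each list, and fry was run beside it. The p of fry tests whether the genes of a list move on balance one way and does not compare them with other genes. Because the median log2 change of all genes was far from 0 in several comparisons, list medians are also given minus that of all genes ("relative to all genes").

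Genes were named by a rule: EIF3G, the genes with the largest change in each direction among those past the threshold whose groups did not overlap (up to 8 for knockdown comparisons and up to 6 for polysomal against input, mean of at least 5 TPM), the 5 with the smallest p in each direction where none passed, and up to 4 members of each list. Some genes that this rule names are not reported here. Groups, tests, lists, the naming rule and most alternative settings were chosen before the data were examined. These settings were a pseudocount of 0.1 or 5; no filter, or a minimum of 5 TPM; rescaling by median-of-ratios size factors, quantile normalization, and a total without ribosomal protein genes; the fit without the trend or with robust moderation; only the groups compared; the replicate number as a block; each library, and each replicate number, left out; and the other list tests.

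Further alternatives were chosen after seeing the data, because 3 libraries stood apart from their groups. Each library's position along the first axis of the deviations from the group means was added to the model as a covariate (the axis term, 7 residual degrees of freedom). The axis partly coincides with the fraction, so for polysomal against input the fit with the axis term gives a count of genes only. It also separated the siRNA groups in polysomal RNA. Positions were 48.77 to 95.95 in siCtrl polysomal and -25.98 to 39.9 in siEIF3G polysomal libraries. There the axis term may take up part of a knockdown effect. The fits were also run without those 3 libraries, and without the 2 knockdown libraries numbered 3. On simulated data with 200 changed genes among 10605 and the spread of these libraries, the group-mean fit recovered 51.2% of 4-fold changes and 4.85% of 2-fold changes in input RNA. The fit with the axis term recovered 94.8% and 57.3%. In that comparison 1.58% of the calls were false in the group-mean fit, and 5.24% with the axis term. For polysome loading the group-mean fit recovered 12.1% of 4-fold changes. The simulation drew axis positions independently of the groups and the remaining spread independently for each gene, as the fit with the axis term assumes. In the real libraries neither need hold, so these rates do not measure how reliable the real calls with the axis term are. Plots were drawn with matplotlib 3.10.9.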

Results

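Gene expression was measured in 12 libraries of H1299 cells, with 3 libraries for each of siCtrl input, siEIF3G input, siCtrl polysomal and siEIF3G polysomal RNA. EIF3G encodes an RNA-binding subunit of eIF3, the complex that brings mRNA to the small ribosomal subunit. Between 13787 and 14659 genes were above 0 TPM in a library, and the depth of the libraries is unknown because TPM keep no read counts. The mRNAs of cytosolic ribosomal proteins, the building blocks of the translation machinery, took between 22.9% and 39.3% of a library. MTRNR2L2, a near copy of mitochondrial ribosomal RNA, ranged from 1258 to 2735 TPM in the 6 input libraries and from 5.41 to 13.1 TPM in the 6 polysomal ones, so each library carried the mark of its labelled fraction. In 3 libraries the other genes placed the library nearer to the other fraction of the same siRNA, by mean Pearson correlation across genes, which are not independent replicates. These were siCtrl input 1 (0.922 with its own group and 0.957 with the other fraction), siEIF3G input 2 (0.928 and 0.958) and siEIF3G polysomal 3 (0.949 and 0.953). The first axis of the deviations from the group means held 78.0% of the variance within groups.

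**Figure D1:**
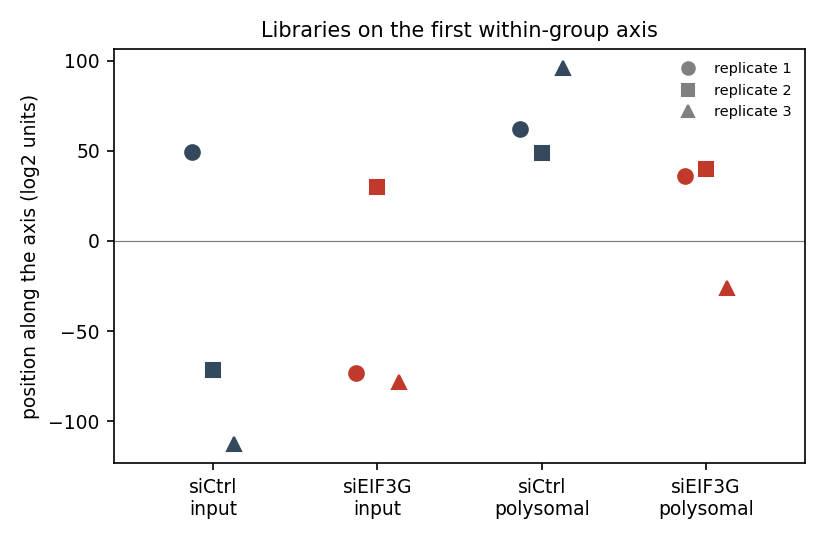
Position of each library along the first axis of the deviations from the group means, in log2 units (y axis), by group (x axis), with 1 point per library and the marker giving the replicate number. siCtrl input 1 (49.4) and siEIF3G input 2 (30.2) lay above 0 with the polysomal libraries, and siEIF3G polysomal 3 (-25.98) lay below 0 with the other inputs.

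The knockdown itself was large in both fractions. EIF3G fell from 1043 ± 147 TPM to 64.3 ± 18.9 TPM in input RNA (SD, n = 3 libraries each), so 6.16% remained. In polysomal RNA it fell from 1800 ± 118 TPM to 115 ± 39.9 TPM, and 6.38% remained. The limma log2 fold change was -4.03 in input RNA (SE 0.29, adjusted p = 3.71e-05) and -4.02 in polysomal RNA (SE 0.29, adjusted p = 3.76e-05). All 3 knockdown libraries lay below all 3 control libraries in each fraction. The knockdown effect on EIF3G differed by 0.00 between polysomal and input RNA (SE 0.41, adjusted p = 0.998), which is -0.38 relative to all genes as deposited and 0.08 with quantile normalization. EIF3G is on chromosome 19, at positions 10115014 to 10119899. With size factors in place of the deposited scaling, the input value of -3.98 had an adjusted p of 0.0657, against a range of 1.49e-06 to 0.0657 over its alternatives.

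**Figure D2:**
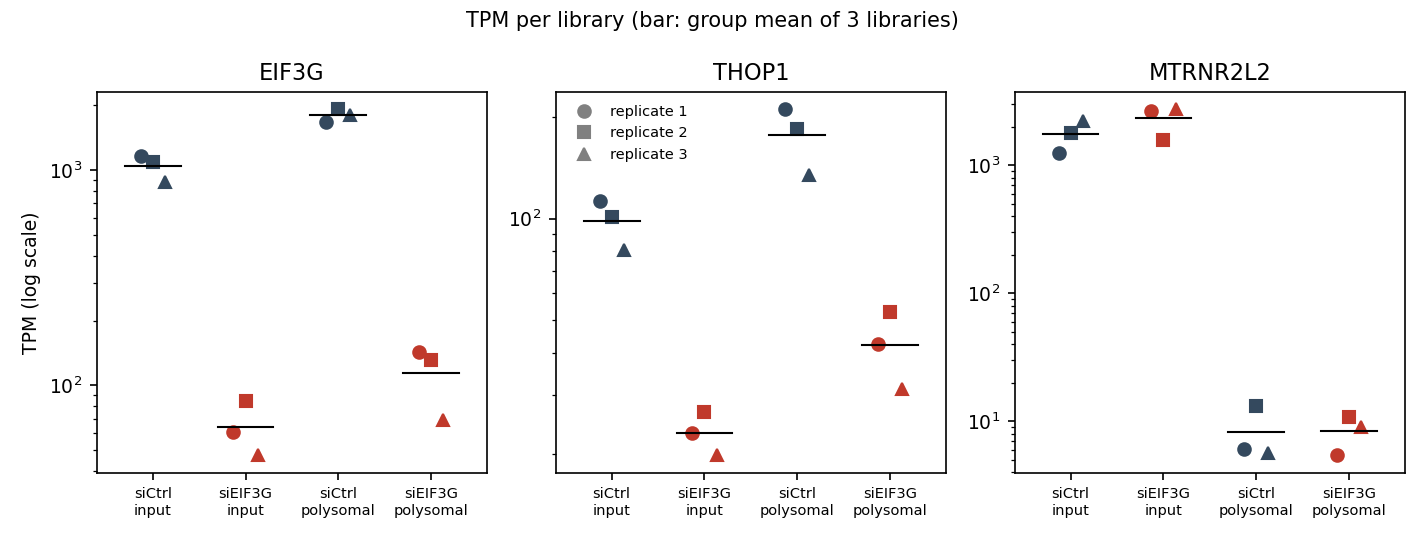
TPM per library (y axes, log scale) of EIF3G, THOP1 and MTRNR2L2 in the 4 groups (x axes), with the bar at the mean of 3 libraries and the marker giving the replicate number. EIF3G and THOP1 were lower in every knockdown library than in every control library of the same fraction, and MTRNR2L2 separated the 6 input libraries from the 6 polysomal ones.

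Knockdown against control in input RNA shows which mRNAs changed in level in the whole lysate. Beside EIF3G, THOP1 fell. It encodes thimet oligopeptidase, an enzyme that cleaves short peptides, and is on chromosome 19 at positions 2785503 to 2815807. THOP1 went from 98.3 ± 16.4 TPM to 23.1 ± 3.42 TPM (SD, n = 3 libraries each), a log2 fold change of -2.04 (SE 0.28, adjusted p = 0.03). It was lower in all 3 knockdown libraries than in all 3 control libraries. Whether the siRNAs match THOP1, or any gene other than EIF3G, in sequence was not tested. EIF3G and THOP1 were the 2 genes called by limma among 10605, both lower with the deposited scaling. With size factors the calls were 1 higher and 0 lower, and with quantile normalization 1 higher and 1 lower. At an unadjusted p under 0.05 were 144 genes, where 530.2 would be expected by chance. EGR1, a transcription factor of the immediate early response, was at 4.56 ± 2.30 TPM in control and 29.6 ± 15.8 TPM in knockdown input. Its log2 fold change was 2.44 (SE 0.52, adjusted p = 0.672). EGR1 passed with size factors (2.41, SE 0.32, adjusted p = 0.0228) and without the 3 libraries that stood apart (2.34, SE 0.35, adjusted p = 0.0438).

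Among the gene lists in input RNA, 3 lists tied to signalling and stress stood above the other genes by camera. Of all tested genes, 42.95% were positive in input RNA. Immediate early genes, which answer growth factors and stress within minutes, were positive in 15 of 17 members, with a median of 0.52 (0.57 relative to all genes; adjusted p = 8.57e-16, and adjusted p = 0.0824 with an estimated correlation). No member passed over all genes, and 3 passed when adjusted over the list alone: EGR1, IER2 (0.97, SE 0.23) and FOS (1.18, SE 0.36). Targets of ATF4, the transcription factor of the integrated stress response, were positive in 30 of 33 members, with a median of 0.48 (0.53 relative to all genes; adjusted p = 2.58e-08, and adjusted p = 0.901 with an estimated correlation). DDIT3, a pro-apoptotic factor of that response, was at 1.45 (SE 0.64) and SESN2, a stress-induced inhibitor of mTOR signalling, at 1.24 (SE 0.55), neither past the threshold. The ATF4 list, relative to all genes, was at 0.07 without siEIF3G input 3 (adjusted p = 0.358) and at 0.833 without siEIF3G input 1. Inflammatory cytokines and targets of NF-kB were positive in 6 of 7 members, with a median of 0.35 (adjusted p = 2.47e-05, and adjusted p = 0.0824 with an estimated correlation), among them the chemokine CCL2 at 0.89 (SE 0.33). That list, at 0.40 relative to all genes, was at 0.616 without siCtrl input 1, 0.202 without siCtrl input 3, 0.685 without siEIF3G input 1 and 0.23 without siEIF3G input 2, and it passed each time.

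**Figure D3:**
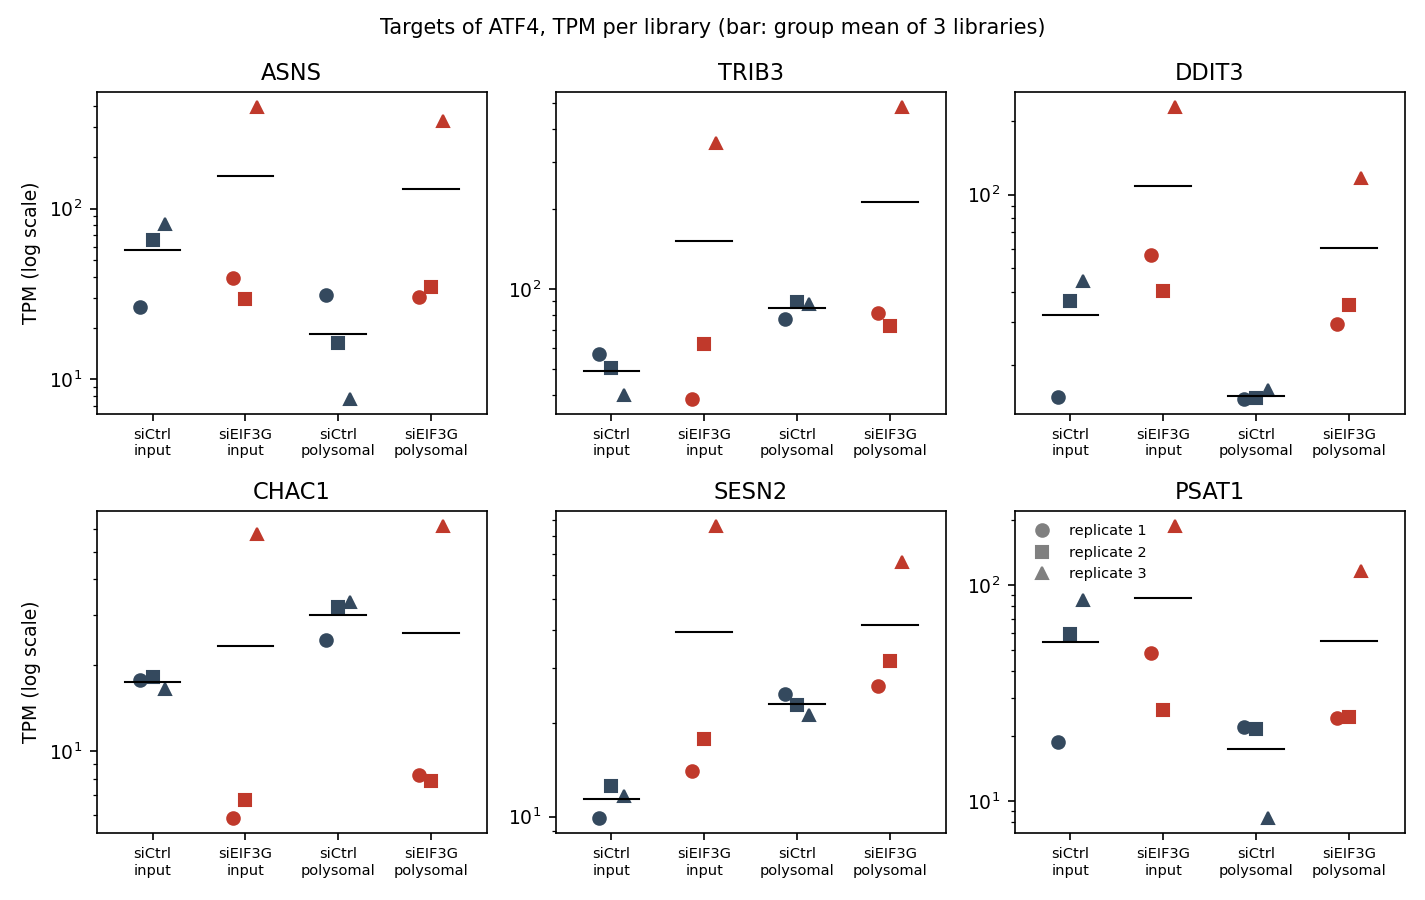
TPM per library (y axes, log scale) of the ATF4 targets ASNS, TRIB3, DDIT3, CHAC1, SESN2 and PSAT1 in the 4 groups (x axes), with the bar at the mean of 3 libraries and the marker giving the replicate number. In the knockdown libraries numbered 3, ASNS reached 396 TPM in input and 326 TPM in polysomal RNA, against 29.6 to 39.2 TPM in the other 4 knockdown libraries.

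Genes of ribosome production also stood above the other genes in input RNA. The mRNAs of cytosolic ribosomal proteins were positive in 74 of 84 members, with a median of 0.29 (0.34 relative to all genes; adjusted p = 4.22e-16, and adjusted p = 0.0824 with an estimated correlation). No member passed over all genes or over the list alone, and the members named were RPL21 at 0.61 (SE 0.32) and RPL37A at 0.59 (SE 0.22). The relative value was 0.617 without siCtrl input 1, 0.198 without siCtrl input 2, 0.066 without siCtrl input 3 and 0.171 without siEIF3G input 2, and the list passed each time. Ribosome biogenesis factors, which process ribosomal RNA and assemble subunits, were positive in 41 of 46 members, with a median of 0.20 (adjusted p = 0.000183, and adjusted p = 0.901 with an estimated correlation). UTP4 was at 0.77 (SE 0.52) and NOB1 at 0.67 (SE 0.40). The biogenesis list, at 0.25 relative to all genes, was at 0.01 without siCtrl input 1, 0.395 without siCtrl input 3, 0.553 without siEIF3G input 2 and 0.08 without siEIF3G input 3 (adjusted p = 0.0542), which alone ended the call.

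The lists below the other genes in input RNA were 3. Cholesterol biosynthesis was negative in 22 of 25 members, with a median of -0.44 (-0.39 relative to all genes; adjusted p = 7.91e-07, and adjusted p = 0.467 with an estimated correlation). IDI1, an isomerase of the isoprenoid pathway, was at -1.24 (SE 0.57) and HMGCS1, which makes the precursor of mevalonate, at -0.75 (SE 0.75). Mitosis genes were negative in 37 of 40 members, with a median of -0.40 (adjusted p = 0.000341, and adjusted p = 0.901 with an estimated correlation). The kinetochore protein CENPF was at -1.05 (SE 0.84) and the proliferation marker MKI67 near -1 (SE 0.77). Heat shock proteins, which fold other proteins (a list that includes the mitochondrial HSPD1 and HSPE1), were negative in 11 of 14 members, with a median of -0.26 (adjusted p = 0.00622, and adjusted p = 0.901 with an estimated correlation). HSPA1A at -1.22 (SE 0.60) and HSPA1B at -1.13 (SE 0.57) are near copies that share reads. The mitosis call ended without siCtrl input 3 (adjusted p = 0.074) or siEIF3G input 2 (adjusted p = 0.406), and the heat shock call without the same libraries (adjusted p = 0.0874 and 0.09). Mitosis, at -0.35 relative to all genes, was at -0.6 without siCtrl input 1 and -0.144 without siEIF3G input 2. Heat shock, at -0.21, was at -0.439 without siCtrl input 1, -0.352 without siEIF3G input 1 and -0.358 without siEIF3G input 2.

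The other 19 lists did not pass in input RNA, where the median of all genes was -0.05. Some lay as far from it as the heat shock list. The other eIF3 subunits were at 0.15 (adjusted p = 0.0734), other initiation factors at 0.07 and elongation factors at 0.15 (the last with the positive EEF2 at 0.68, SE 0.28, and the negative EIF5A2 at -0.94, SE 0.44). OXPHOS subunits were at -0.07, mitochondrial ribosomal proteins at 0.02, proteasome subunits at -0.12, lysosome genes at 0.06 and autophagy genes at -0.05. Endoplasmic reticulum chaperones were at -0.25, DNA replication genes at -0.05, pro-apoptotic genes at -0.20, anti-apoptotic genes at -0.19 and p53 targets at -0.12. Interferon-stimulated genes were at -0.19, mTOR pathway genes at -0.17, epithelial markers at -0.20 and mesenchymal genes at 0.07. For p53 targets and housekeeping genes (-0.06) the median relative to all genes was negative where the test read higher. Histones were at -0.05, with 1 histone gene, H4C2 (-1.74, SE 0.34), past the threshold when adjusted over the list alone. The 3 tested markers of other cell types had a median of 0.08, with MBP at -0.21 and ACTA2 at 0.15. With an estimated correlation, and with fry, 0 of the 27 lists passed in input RNA, where camera at the preset correlation called 8.

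Limits of the input comparison: groups did not overlap for 390 genes, 3.68% of those tested, where chance gives 10%. The THOP1 call ended without siCtrl input 1, 2 or 3 (adjusted p = 0.15, 0.297 and 0.0622), siCtrl polysomal 1 or 2 (0.0534 and 0.101), siEIF3G input 1, 2 or 3 (0.211, 0.0698 and 0.225) or siEIF3G polysomal 1 (0.0869), at log2 fold changes of -2.17 to -1.93.

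Knockdown against control in polysomal RNA shows which mRNAs changed among those bound by several ribosomes. THOP1 fell again, from 177 ± 39.0 TPM to 42.1 ± 10.8 TPM (SD, n = 3 libraries each), a log2 fold change of -2.05 (SE 0.28, adjusted p = 0.0274) with all 3 knockdown libraries below all 3 control libraries. EIF3G and THOP1 were again the 2 genes called by limma, both lower, and 709 genes were at an unadjusted p under 0.05. The median log2 fold change of all genes was 0.33 with the deposited scaling, -0.03 with size factors and 0.01 with quantile normalization. Relative to that median EIF3G was at -4.36 and THOP1 at -2.39. As deposited, 72.65% of all tested genes were positive. EGR1 went from 0.95 ± 0.35 TPM to 10.2 ± 7.05 TPM, with a log2 fold change of 2.36 (SE 0.52, adjusted p = 0.65).

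Ribosome biogenesis factors stood above the other genes in polysomal RNA, and kept their call with any single library left out. They were positive in 43 of 46 members, with a median of 1.16 (0.82 relative to all genes; adjusted p = 4.37e-06, and adjusted p = 0.829 with an estimated correlation). NOLC1, a nucleolar phosphoprotein, was at 2.03 (SE 0.75) and the RNA helicase DDX21 at 1.98 (SE 0.80), neither past the threshold. Translation initiation factors had a median of 0.90 (0.56 relative to all genes; adjusted p = 0.0126, and adjusted p = 0.829 with an estimated correlation), with the helicase DDX3X at 1.71 (SE 0.76) and EIF5 at 1.58 (SE 0.69). The other eIF3 subunits had a median of 0.85 without passing (adjusted p = 0.0569). The scaffold subunit EIF3C, which shares reads with its near copy EIF3CL, was at 2.29 (SE 0.57), the 1 subunit past the threshold when adjusted over the list alone. Without siEIF3G polysomal 3 the initiation factors were at 0.30 relative to all genes (adjusted p = 0.205).

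Stress and proliferation lists were called in polysomal RNA as well. Immediate early genes had a median of 0.84 (0.50 relative to all genes; adjusted p = 0.00456, and adjusted p = 0.829 with an estimated correlation), and 4 members passed when adjusted over the list alone: EGR1, IER2 at 0.84, FOS at 1.08 and the phosphatase DUSP1 at 1.04. ATF4 targets had a median of 0.71 (0.38 relative to all genes; adjusted p = 0.00456, and adjusted p = 0.829 with an estimated correlation), with the alanyl-tRNA synthetase AARS1 at 2.18 (SE 0.70) and the asparagine synthetase ASNS at 2.09 (SE 1.00). Its relative value was 0.15 without siEIF3G polysomal 3 (adjusted p = 0.205) and 0.566 without siEIF3G polysomal 1. DNA replication genes had a median of 0.67 (0.34 relative to all genes; adjusted p = 0.00456, and adjusted p = 0.829 with an estimated correlation), with the helicase subunits MCM3 at 1.96 (SE 0.67) and MCM6 at 1.73 (SE 0.65). Their relative value was 0.526 without siCtrl polysomal 1, and the call ended without replicate number 2 (adjusted p = 0.062) or 3 (0.0549). Mesenchymal and matrix genes had a median of 0.62 (adjusted p = 0.0283, and adjusted p = 0.829 with an estimated correlation). Members past the threshold when adjusted over the list alone included the integrin ITGB1 at 2.23 (SE 0.69) and vimentin (VIM) at 1.44 (SE 0.46). That call ended without siEIF3G polysomal 1 (adjusted p = 0.0712) or 2 (0.097), and the relative value of 0.28 became 0.18 without siCtrl polysomal 3. Cholesterol biosynthesis was at 0.01, which is -0.32 relative to all genes (adjusted p = 0.0406, and adjusted p = 0.829 with an estimated correlation). It lost its call without siCtrl polysomal 1 (adjusted p = 0.435), siEIF3G polysomal 1 (0.0712) or siEIF3G polysomal 3 (0.136). Its relative value was -0.122 and -0.113 without the first and last of these, -0.548 without siCtrl polysomal 2, -0.499 without siCtrl polysomal 3 and -0.578 without siEIF3G polysomal 2.

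**Figure D4:**
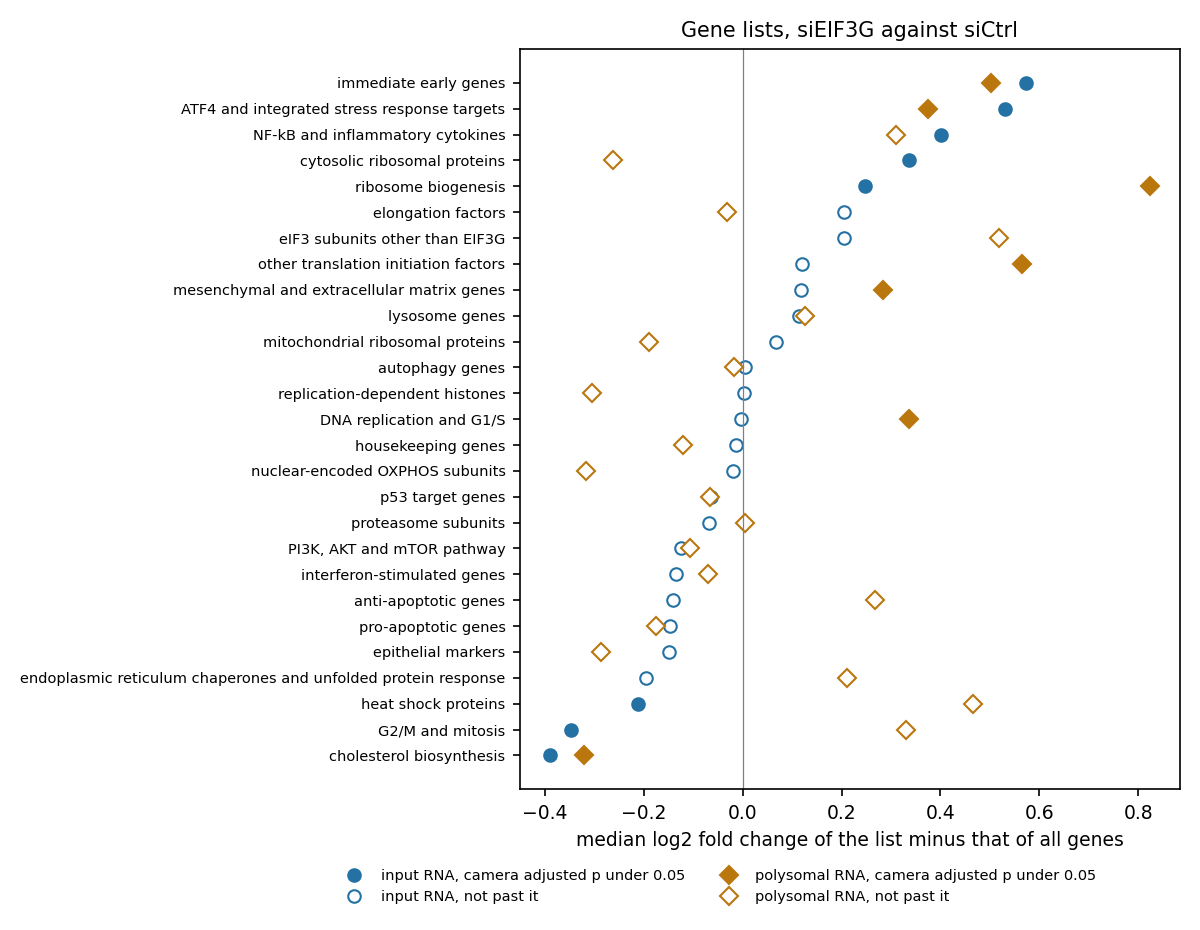
Median log2 fold change of siEIF3G against siCtrl for each of 27 gene lists (y axis) minus the median of all genes (x axis, log2), in input RNA (circles) and polysomal RNA (diamonds), filled where camera at the preset correlation passed. Ribosome biogenesis stood at 0.82 in polysomal RNA, and cytosolic ribosomal proteins at 0.34 in input RNA but at -0.26 in polysomal RNA, where quantile normalization turns the sign to 0.10.

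The other 20 lists did not pass in polysomal RNA. Relative to all genes, cytosolic ribosomal proteins were at -0.26 as deposited, -0.44 with size factors and 0.10 with quantile normalization, so their direction depended on the scaling. Epithelial markers (-0.29), housekeeping genes (-0.12) and elongation factors (-0.03) also turned positive with quantile normalization, and proteasome subunits (0.01) turned negative with size factors. Mitochondrial ribosomal proteins were at -0.19 and at 0 with quantile normalization. For elongation factors and housekeeping genes the test read higher where the relative median was negative. OXPHOS subunits were at -0.32, histones at -0.31, pro-apoptotic genes at -0.18, mTOR pathway genes at -0.11, interferon-stimulated genes at -0.07, p53 targets at -0.07 and autophagy genes at -0.02. The other eIF3 subunits were at 0.52, heat shock proteins at 0.47, mitosis genes at 0.33, inflammatory cytokines at 0.31, anti-apoptotic genes at 0.27, endoplasmic reticulum chaperones at 0.21 and lysosome genes at 0.13. The chaperones HSPA5 at 2.12 (SE 0.70) and HSP90B1 at 1.98 (SE 0.66) were among the members named. The 3 tested markers of other cell types were at -0.14. With an estimated correlation, and with fry, 0 of the 27 lists passed in polysomal RNA, where camera at the preset correlation called 7.

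Limits of the polysomal comparison: groups did not overlap for 3093 genes, 29.2% of those tested (2286 higher and 807 lower), where chance gives 10%, and leaving out siCtrl polysomal 1 raised the number of lists called from 7 to 12. The siCtrl and siEIF3G polysomal libraries also did not overlap along the first axis, so that share cannot be told apart from variation between libraries. The THOP1 call ended without siCtrl polysomal 1, 2 or 3 (adjusted p = 0.171, 0.338 and 0.0542), siEIF3G polysomal 1, 2 or 3 (0.213, 0.0524 and 0.141), siCtrl input 2 (0.0817) or siEIF3G input 1 (0.0667).

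Polysome loading asks whether the knockdown effect differed between polysomal and input RNA, gene by gene. No gene passed: limma called 0 of 10605 genes, 19 were at an unadjusted p under 0.05, and the smallest adjusted p was 0.908. On the side of higher loading the genes with the smallest p included the chaperone HSP90B1 (2.26, SE 0.94), the segregase VCP (1.81, SE 0.76), the RNA helicase SKIV2L (1.11, SE 0.47) and beta-catenin, CTNNB1 (2.07, SE 0.91). On the side of lower loading they were the linker histone H1-2 (-1.08, SE 0.36), the ribosomal protein RPL29 (-0.58, SE 0.24), the ubiquitin-conjugating enzyme UBE2C (-0.73, SE 0.33), the calcium sensor HPCAL1 (-0.85, SE 0.40) and the cell cycle inhibitor CDKN1A (-0.76, SE 0.37), all of these at an adjusted p of 0.908. The median of all genes was 0.38 as deposited, -0.05 with size factors and -0.01 with quantile normalization. As deposited, 73.87% of all tested genes were positive.

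As a group, the mRNAs of cytosolic ribosomal proteins stood below the other genes in loading. They were negative in 65 of 84 members, with a median of -0.16 (-0.55 relative to all genes; adjusted p = 3.01e-16, and adjusted p = 0.181 with an estimated correlation). Quantile normalization left -0.11 relative to all genes (adjusted p = 0.0897). Their share of a library ranged from 28.5% to 36.4% in control input, 33.8% to 39.3% in knockdown input, 22.9% to 28.3% in control polysomal and 25.7% to 27.6% in knockdown polysomal RNA. Mitosis genes stood above the other genes, with a median of 1.22 (0.84 relative to all genes; adjusted p = 0.000273, and adjusted p = 0.922 with an estimated correlation), the kinesin KIF20A at 1.75 (SE 0.94) and the topoisomerase TOP2A at 1.71 (SE 1.07). DNA replication genes had a median of 0.80 (0.41 relative to all genes; adjusted p = 0.000273, and adjusted p = 0.922 with an estimated correlation), with MCM3 at 1.83 (SE 0.95). Endoplasmic reticulum chaperones were positive in 22 of 23 members, with a median of 0.68 (adjusted p = 0.00325, and adjusted p = 0.922 with an estimated correlation) and CANX at 1.89 (SE 1.00). Ribosome biogenesis factors had a median of 0.99 (adjusted p = 0.00703), initiation factors of 0.76 (adjusted p = 0.0369) and heat shock proteins of 1.11 (adjusted p = 0.0386), each with adjusted p = 0.922 with an estimated correlation.

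These loading values depended on single libraries (values relative to all genes). Cytosolic ribosomal proteins were at -0.996 without siCtrl input 1 and -0.346 without siCtrl input 3, with a range of -1.268 to -0.182 once whole replicate numbers are included, and passed each time. Mitosis genes were at 0.531 without siCtrl input 3, 0.536 without siCtrl polysomal 3 and 0.452 without siEIF3G input 2, and DNA replication genes at 0.24 without siCtrl polysomal 3, all past the threshold. Endoplasmic reticulum chaperones were at 0.448 without siCtrl input 1 and lost their call without siEIF3G polysomal 2 (adjusted p = 0.054). Ribosome biogenesis lost its call without siCtrl input 1 (adjusted p = 0.0612), siCtrl polysomal 3 (0.122), siEIF3G input 1 (0.0584) or siEIF3G polysomal 2 (0.0528), and was at 0.402, 0.372, 0.287 and 0.359 without siCtrl input 3, siCtrl polysomal 3, siEIF3G input 2 and siEIF3G polysomal 3. Initiation factors, at 0.38, lost their call under 14 of 32 alternatives and were at -0.006 with the axis term (adjusted p = 0.488, of a range from 0.00396 to 0.922). The libraries that ended it were siCtrl input 1 (0.0612) and 3 (0.0743), siCtrl polysomal 3 (0.0889), siEIF3G input 1 (0.0649) and 2 (0.151) and siEIF3G polysomal 3 (0.564), the value being 0.224, 0.183 and 0.131 without siCtrl input 3, siEIF3G input 2 and siEIF3G polysomal 3. Heat shock proteins, at 0.73, also lost their call under 14 of 32, among them without siCtrl input 1 (0.135), siCtrl polysomal 2 (0.058) and 3 (0.108, at 0.406), siEIF3G input 1 (0.0584) and 3 (0.162) and siEIF3G polysomal 1 (0.0825) and 2 (0.491).

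The other 20 lists did not pass in loading. Relative to all genes, inflammatory cytokines were at -0.52, immediate early genes at -0.36 (adjusted p = 0.0705), histones at -0.22, pro-apoptotic genes at -0.19, ATF4 targets at -0.15, interferon-stimulated genes at -0.14, autophagy genes at -0.10, mTOR pathway genes at -0.06 and p53 targets at -0.01. The other eIF3 subunits were at 0.30, mesenchymal genes at 0.27 (adjusted p = 0.0705) and anti-apoptotic genes at 0.14. OXPHOS subunits (-0.28), mitochondrial ribosomal proteins (-0.24), epithelial markers (-0.14), elongation factors (-0.11) and housekeeping genes (-0.09, where the test read higher) turned positive with quantile normalization. Cholesterol biosynthesis (0.08), proteasome subunits (0.09) and lysosome genes (0.03) turned negative with size factors. The 3 markers of other cell types were at -0.20. With an estimated correlation, and with fry, 0 of the 27 lists passed in loading, where camera at the preset correlation called 7. The number of lists called was 15 without siCtrl polysomal 1, 13 without siEIF3G polysomal 3, and 4 without siCtrl polysomal 3 or without siEIF3G polysomal 2.

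The changes in input and polysomal RNA were compared across genes, which are not independent replicates. Across the 10605 genes the log2 fold changes had a Pearson correlation of 0.399 and a Spearman correlation of 0.345, with a slope of polysomal on input change of 0.692. The Pearson value was -0.207 without siCtrl input 1 and -0.0094 without siEIF3G input 3, so its sign rested on single libraries. Both called genes, EIF3G and THOP1, were lower in both fractions, where 0.000377 shared genes would be expected by chance.

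With the axis term, which was added after seeing the data, 24 genes were called in input RNA (5 higher and 19 lower, 1229 at an unadjusted p under 0.05) and 10 in polysomal RNA (4 higher and 6 lower, 1316 unadjusted). These genes were singled out after their values were seen. In polysomal RNA the axis also separated siCtrl from siEIF3G libraries, and the median change of all genes went from 0.33 to -0.06. The polysomal effects with the axis term therefore cannot be told apart from what the axis takes up. EGR1 rose by 2.48 in input RNA (SE 0.28, adjusted p = 0.00126) and by 1.85 in polysomal RNA (SE 0.30, adjusted p = 0.0316), and the transcriptional coregulator IFRD1 by 1.47 (adjusted p = 0.00929) and 1.65 (adjusted p = 0.0151). FOS rose in input RNA (1.20, SE 0.20, adjusted p = 0.027), and APP, the precursor of amyloid beta, rose in polysomal RNA (1.51, SE 0.24, adjusted p = 0.0316). ACHE, acetylcholinesterase, rose in both fractions, by 0.78 and 0.98. ABHD17A, an enzyme that removes palmitate from membrane proteins, fell in input RNA (-2.20, SE 0.24, adjusted p = 0.00126) and in polysomal RNA (-1.61). DDAH1, which breaks down methylated arginine, fell by 1.75 and 1.66, the kinase gene MAPK6 by 1.74 and 1.59, and NSMCE4A, a subunit of a DNA repair complex, by 1.12 and 1.25. In input RNA C16orf74 (-1.77), the small GTPase HRAS (-1.28), the histone genes H4C2 (-1.72) and H3C7 (-1.33), RDH11 (-1.30), ANKRD1 (-1.17) and the translation factor EIF5A2 (-0.90) also fell. All 24 genes called in input RNA had the same sign in polysomal RNA. In both, 3 higher and 6 lower genes were called, EIF3G among the lower ones. Independent comparisons would share 0.00189 and 0.0107, but these comparisons share 1 estimate of the spread per gene and are not independent. Loading again had 0 genes called by limma, with 208 at an unadjusted p under 0.05. The correlation of the changes across genes was 0.619.

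**Figure D5:**
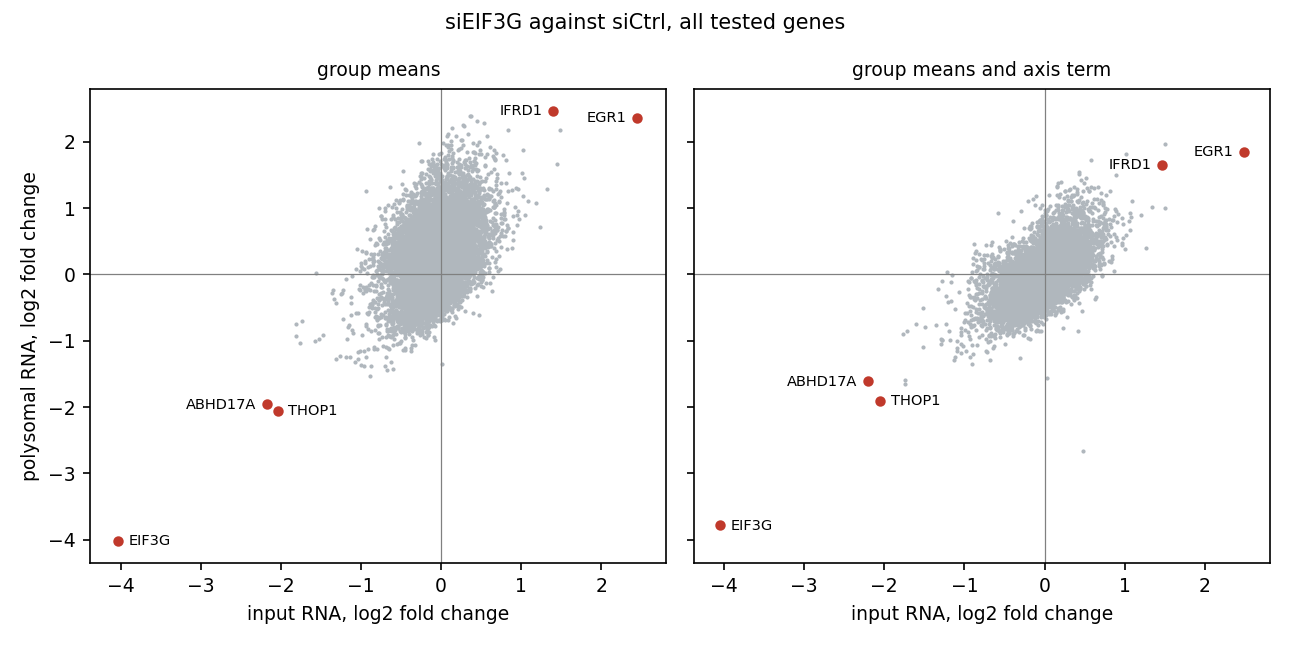
Log2 fold change of siEIF3G against siCtrl in input RNA (x axis) and polysomal RNA (y axis), with 1 point per tested gene, from the fit of group means (left) and with the axis term (right). EIF3G, THOP1 and ABHD17A lay at the lower left and EGR1 and IFRD1 at the upper right in both, and the correlation across genes was 0.399 on the left and 0.619 on the right.

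Limits of the fit with the axis term: leaving out 1 library moved the input count from 24 to 8 (siCtrl input 2), 6 (siCtrl input 3), 393 (siEIF3G input 1), 6 (siEIF3G input 2), 7 (siEIF3G input 3), 13 (siEIF3G polysomal 1) or 38 (siEIF3G polysomal 3). The polysomal count of 10 moved to 4 (siCtrl input 1, 2 or 3), 370 (siCtrl polysomal 1), 1 (siCtrl polysomal 2), 2 (siCtrl polysomal 3), 1 (siEIF3G input 2), 1 (siEIF3G polysomal 1) or 4 (siEIF3G polysomal 2).

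Single genes of the fit with the axis term were also rerun under 27 alternatives, and no sign changed. In input RNA EGR1 (adjusted p = 0.000178 to 0.0207) and C16orf74 passed in all 27. ABHD17A and THOP1 lost their calls in 1 (adjusted p up to 0.112 each), HRAS in 6 (up to 1), NSMCE4A in 11 (up to 0.779) and DERL2, which acts in protein degradation at the endoplasmic reticulum and fell by 1.04, in 11 (up to 0.877). In polysomal RNA the calls were less stable. THOP1 lost its call in 6 (up to 0.32), IFRD1 in 11 (up to 0.266), EGR1 in 15 (up to 0.309), ABHD17A in 17 (up to 0.817), NSMCE4A in 17 (up to 0.969) and APP in 18 (up to 0.639). The other genes named with the axis term were not rerun one by one.

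With the axis term more members of several lists passed when adjusted over the list alone, and 3 of these lists are given here. Of the mitosis genes, 11 of 40 fell in input RNA when adjusted over the list alone and 0 over all genes, among them the cyclin-dependent kinase CDK1 (-0.80), CENPF (-0.96), CENPE (-0.86) and MKI67 (-0.92). The list had adjusted p = 5.19e-07, and adjusted p = 0.23 with an estimated correlation. Of the cholesterol biosynthesis genes, 7 of 25 fell in input RNA when adjusted over the list alone and 0 over all genes, among them IDI1 (-1.18), MVD (-0.75) and INSIG1 (-0.59). That list had adjusted p = 1.21e-06, and adjusted p = 0.367 with an estimated correlation. In polysomal RNA 17 of 46 ribosome biogenesis factors rose and 1 fell when adjusted over the list alone, among them UTP14A (1.09), NOLC1 (1.05) and nucleolin, NCL (0.88). Their list had adjusted p = 1.39e-12, and adjusted p = 0.441 with an estimated correlation.

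Polysomal against input RNA in control cells shows which mRNAs were over-represented on polysomes before any knockdown. POLR2G, a subunit of RNA polymerase II, rose from 184 ± 14.2 TPM in input to 856 ± 33.7 TPM on polysomes (SD, n = 3 libraries each), a log2 fold change of 2.21 (SE 0.21, adjusted p = 0.000214). The proteasome subunits PSMB6 (1.85, SE 0.18, adjusted p = 0.000198) and PSMB3 (1.85, SE 0.20, adjusted p = 0.000696) and the mitochondrial ribosomal protein MRPL27 (1.79, SE 0.20, adjusted p = 0.000696) rose as well. EIF3CL (4.04, SE 0.87) and GAGE12J (1.92, SE 0.26) rose too, but share reads with near copies, which leaves their values uncertain. Lower on polysomes were the DNA repair kinase PRKDC (-3.77, SE 0.84, adjusted p = 0.0184), the splicing factor SON (-3.36, SE 0.76), TAF13 of the transcription machinery (-3.31, SE 0.64), HSP90B1 (-3.28, SE 0.66, from 119 to 9.81 TPM), TOP2A (-3.27, SE 0.76) and the poly(A)-binding protein PABPC1 (-3.25, SE 0.71). In all, limma called 3912 genes, 846 higher and 3066 lower, which is 21.6% higher. The median of all genes was -0.96 as deposited, -0.04 with size factors and -0.09 with quantile normalization, and the share of calls that were higher was 62.2% and 57.1% with these scalings. Relative to all genes POLR2G was at 3.18, PSMB6 at 2.82, HSP90B1 at -2.31 and PRKDC at -2.80, with no change of sign under the other scalings.

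Camera called 4 lists in control cells, all above the other genes on polysomes with the deposited scaling. OXPHOS subunits had a median of 0.08 (1.04 relative to all genes, but 0.06 with quantile normalization; adjusted p = 0.00243, and adjusted p = 0.958 with an estimated correlation), a mean of -0.04 with the opposite sign, and 13 members higher and 9 lower over all genes (13 and 8 adjusted over the list alone). NDUFS3 (1.55) and NDUFB8 (log2 1.5) were higher and NDUFC1 (-2.24) lower, all 3 subunits of respiratory complex I. Lysosome genes had a median of 0.29 (1.26 relative to all genes, 0.48 with quantile normalization; adjusted p = 0.0101, and adjusted p = 0.958 with an estimated correlation) and a mean of -0.06, with 7 higher and 5 lower over all genes and when adjusted over the list alone. Mitochondrial ribosomal proteins were at -0.18 (0.78 relative to all genes; adjusted p = 0.0101, and adjusted p = 0.958 with an estimated correlation), with 15 higher and 8 lower (14 and 8 adjusted over the list alone). Their relative sign turned to -0.06 with quantile normalization. Proteasome subunits were at -0.18 (0.78 relative to all genes; adjusted p = 0.0101, and adjusted p = 0.958 with an estimated correlation), with 7 higher and 2 lower by either adjustment, and turned to -0.17 with quantile normalization.

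The lists with most calls to the lower side in control cells did not pass camera. Mitosis genes were 3 higher and 24 lower over all genes, of 40 (3 and 29 adjusted over the list alone), with ANLN, a scaffold of cell division, at -2.89 and KIF20A at -2.84. Initiation factors were 1 higher and 19 lower of 37 (1 and 22 adjusted over the list alone), and ribosome biogenesis factors 7 higher and 17 lower of 46 (7 and 27). DNA replication genes were 0 higher and 14 lower of 41 (0 and 14), with MCM4 at -3.05 (SE 0.56, adjusted p = 0.00924), by limma. Chaperones of the endoplasmic reticulum were 1 higher and 7 lower of 23 (1 and 11), with HSPA5 at -2.85, and heat shock proteins 1 higher and 7 lower of 14 (1 and 7), with HSPH1 at -3.02. Mesenchymal genes were 0 higher and 9 lower of 20 (0 and 11), with VIM at -1.98 (1795 to 438 TPM). The other eIF3 subunits were 2 higher and 6 lower of 13 (2 and 7), with EIF3A at -3.10. Cytosolic ribosomal proteins were 4 higher and 22 lower of 84 (3 and 15), and relative to all genes their median was 0.63 as deposited but -0.34 with quantile normalization.

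For the remaining lists in control cells the medians relative to all genes, and the members higher and lower over all genes, were as follows. Cholesterol biosynthesis was at 1.00 with 5 and 5, housekeeping genes at 0.78 with 1 and 1 (GAPDH at 0.90 higher), p53 targets at 0.77 with 4 and 3, and interferon-stimulated genes at 0.76 with 3 and 5. ATF4 targets were at 0.60 with 3 and 6, epithelial markers at 0.51 with 1 and 2, inflammatory cytokines at 0.41 with 1 and 2 (CXCL2 at -1.92), histones at 0.40 with 1 and 3, and immediate early genes at 0.25 with 2 and 2 (MYC at -1.81 and IER2 at 1.3). The mTOR pathway was at 0.22 with 3 and 8 (MTOR itself at -2.27), a sign that turned with quantile normalization, as those of DNA replication (-0.11) and autophagy genes did with size factors. Pro-apoptotic genes were at 0.15 with 2 and 3, elongation factors at -0.01 with 1 and 4, autophagy genes at -0.13 with 3 and 9, and anti-apoptotic genes at -0.73 with 0 and 5. The 3 markers of other cell types were at 0.94 with none called. With an estimated correlation, and with fry, 0 of the 27 lists passed, where camera at the preset correlation called 4, and 2 without siCtrl polysomal 1.

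Limits of this comparison: the 3912 calls became 7185 without siCtrl input 1, 145 without siCtrl input 2, 175 without siCtrl input 3, 227 without siCtrl polysomal 1, 130 without siCtrl polysomal 2, 273 without siCtrl polysomal 3, 2408 without siEIF3G input 3, 1097 without siEIF3G polysomal 1 and 1545 without siEIF3G polysomal 2. Without the 3 libraries that stood apart, which was tried after seeing the data, 7960 genes were called (1407 higher and 6553 lower). The lower side was not particular to polysomal RNA. For 3258 genes lower on polysomes outside those 3 libraries, siCtrl input 1 lay a median share of 0.96 of the way from input to polysomal values. For 671 higher genes that share was 0.043. Whether the lower side reflects binding to polysomes or a difference between libraries was not tested.

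Polysomal against input RNA in knockdown cells asks the same of cells with little EIF3G. POLR2G (2.03, SE 0.21, adjusted p = 0.000491) and PSMB6 (1.71, SE 0.18, adjusted p = 0.000405, from 661 to 2158 TPM) rose, as did the mitochondrial enzymes IDH3B (1.77, SE 0.34) and ETFB (1.72, SE 0.20). EIF3CL (4.10) and NME1-NME2 (1.71) rose too and share reads with near copies. Lower on polysomes were TAF13 (-2.64, SE 0.64), the prefoldin subunit PFDN4 (-2.57, SE 0.44), RNF11 (-2.48, SE 0.51), KIAA1191 (-2.46, SE 0.35), the polymerase subunit POLR2K (-2.42, SE 0.38) and SMIM27 (-2.39, SE 0.35). In all, limma called 333 genes, 192 higher and 141 lower, which is 57.7% higher. The median of all genes was -0.49 as deposited, 0.01 with size factors and -0.05 with quantile normalization, and the share of calls that were higher was 38.3% and 38% with these scalings.

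In knockdown cells 6 lists stood above the other genes on polysomes and 1 below. Proteasome subunits had a median of 0.34 (0.83 relative to all genes, 0.21 with quantile normalization; adjusted p = 7.02e-06, and adjusted p = 0.86 with an estimated correlation), with 5 of 33 members higher, among them PSMB5 at 1.48, and none lower (5 adjusted over the list alone). Lysosome genes had a median of 0.54 (1.04 relative to all genes, 0.57 with quantile normalization; adjusted p = 6.7e-05, and adjusted p = 0.86 with an estimated correlation), with the proton pump subunit ATP6V0D1 (1.48) and the protease CTSD (1.10) higher (5 adjusted over the list alone). OXPHOS subunits had a median of 0.14 (0.63 relative to all genes, but 0.05 with quantile normalization; adjusted p = 0.000295, and adjusted p = 0.86 with an estimated correlation), with 7 higher and 4 lower (15 and 7 adjusted over the list alone). Cholesterol biosynthesis had a median of 0.26 (0.75 relative to all genes, 0.43 with quantile normalization; adjusted p = 0.00289, and adjusted p = 0.86 with an estimated correlation), with PMVK (1.69), EBP (1.29) and FDPS (1.24) higher (5 adjusted over the list alone). Mitochondrial ribosomal proteins were at -0.12 (0.37 relative to all genes, -0.08 with quantile normalization; adjusted p = 0.00996, and adjusted p = 0.86 with an estimated correlation), with 6 higher and 2 lower (10 and 3 adjusted over the list alone). Housekeeping genes were at 0.35 (0.85 relative to all genes, 0.36 with quantile normalization; adjusted p = 0.0325, and adjusted p = 0.932 with an estimated correlation).

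Cytosolic ribosomal proteins were the list below the other genes in knockdown cells, with a median of -0.48 (adjusted p = 0.00975, and adjusted p = 0.86 with an estimated correlation). Their relative median of 0.01 had the opposite sign to the test and was -0.50 with quantile normalization. Of the 84 members 0 were higher and 13 lower over all genes by limma, at the adjusted threshold, against 2 higher and 26 lower when adjusted over the list alone. RPL23A (-2.11, SE 0.23, adjusted p = 0.000704), RPL39 (-1.75), RPS29 (-1.70) and RPL26 (-1.57) were the largest. Fry called this list as well (adjusted p = 0.0304), the 1 list it called in any comparison of the group-mean fit.

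For the other 20 lists in knockdown cells the medians relative to all genes lay between -0.32 for anti-apoptotic genes and 0.47 for interferon-stimulated genes, and the 3 markers of other cell types were at 0.58. ATF4 targets were at 0.42 (SHMT2 at 1.31 higher), p53 targets at 0.34, heat shock proteins at 0.29, histones at 0.14 (H2BC12 at -1.16 lower), DNA replication genes at 0.13 and epithelial markers at 0.08. The mTOR pathway was at 0.04 (LAMTOR2 at 1.36 higher), inflammatory cytokines at 0.03 (CXCL2 at -2.18 lower), ribosome biogenesis factors at 0.02 (2 higher and 1 lower) and endoplasmic reticulum chaperones at 0.01. Pro-apoptotic genes were at -0.01, autophagy and immediate early genes at -0.03 each (IER2 at 1.16 higher), elongation factors and the other eIF3 subunits at -0.13 each (EIF3CL higher), mitosis genes at -0.17, mesenchymal genes at -0.19 and initiation factors at -0.20 (EIF2D at -1.33 lower). With quantile normalization heat shock proteins, histones, DNA replication genes, the mTOR pathway, inflammatory cytokines, ribosome biogenesis factors and endoplasmic reticulum chaperones turned negative. With size factors epithelial markers turned negative and pro-apoptotic and immediate early genes positive.

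Limits of this comparison: the 333 calls became 785 without siCtrl input 1, 171 without siCtrl input 2, 149 without siCtrl polysomal 2, 61 without siEIF3G input 1, 150 without siEIF3G input 3, 44 without siEIF3G polysomal 1, 76 without siEIF3G polysomal 2 and 788 without siEIF3G polysomal 3. Without the 3 libraries that stood apart, 7541 genes were called (1734 higher and 5807 lower), and the difference between 3912 and 333 calls in control and knockdown cells is not itself a test, for which the loading comparison gave 0 genes. As in control cells, the lower side also appeared in an input library, siEIF3G input 2 (median share 0.877, against 0.18 for higher genes).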

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

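Of the tests reported here, the one of ribosomal protein mRNAs under other scalings was chosen only after the result was seen, and the axis used as a covariate was defined after the data were seen.

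In 7 gene lists the knockdown effect differed between polysomal and input RNA, by camera at the preset correlation on the interaction of siRNA and fraction. The mRNAs of cytosolic ribosomal proteins had a median log2 difference of -0.165 (65 of 84 genes negative, adjusted p = 3.01e-16). The other 6 lists lay higher: mitosis genes at 1.22 (35 of 40 positive, adjusted p = 0.000273), heat shock proteins at 1.111 (11 of 14, adjusted p = 0.0386), ribosome biogenesis factors at 0.988 (39 of 46, adjusted p = 0.00703), DNA replication genes at 0.796 (36 of 41, adjusted p = 0.000273), translation initiation factors at 0.759 (35 of 37, adjusted p = 0.0369) and endoplasmic reticulum chaperones at 0.682 (22 of 23, adjusted p = 0.00325). Over all tested genes the median was 0.384 and 73.87% were positive, so a majority of positive members does not by itself set a list apart. With a correlation estimated for each list none passed (adjusted p = 0.181 for ribosomal proteins and 0.922 for the others), nor did fry call any. Among all splits of the siRNA labels within each fraction, 100 were drawn. As many lists as the real 7 were called in 37 of the 100, up to 13, so chance is not excluded for this count.

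The lower polysome loading of ribosomal protein mRNAs in knockdown cells, -0.55 relative to other mRNAs (SE 0.39), was weighed as 1 pattern. Size factors (-0.68) and a total without ribosomal protein genes (-0.58) left the median of this list relative to all genes as low as the deposited -0.55, but a factor per library moves all genes nearly alike and decides little. Quantile normalization, which gives every library the same distribution, left -0.11 and a camera adjusted p of 0.0897, the highest of the 3, so the settings differ and an effect of scaling stays open. With the position of each library on the main axis of variation as a covariate the difference was -0.25 (SE 0.20), and an exact two-sided permutation of the siRNA labels within each fraction gave p = 0.16, where 0.005 is the smallest possible, so variation between libraries stays open too. Lower loading of these mRNAs through loss of EIF3G, the biological explanation that the design names, stays open as well.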

How the results depend on the processing

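The axis term, the fits without the 3 libraries apart and those without both knockdown libraries numbered 3 were chosen only after the results were seen.

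EIF3G stayed past the threshold in polysomal RNA under all 29 alternatives run, at -4.56 to -3.7 (adjusted p = 2.25e-06 to 0.0274). In input RNA it did so under 28 of 29, at -4.25 to -3.83, the exception being size factors (-3.98, adjusted p = 0.0657, the highest of a range from 1.49e-06). THOP1 kept its sign throughout (-2.28 to -1.87 in input RNA, -2.59 to -1.86 in polysomal RNA) and lost its call under 18 and 16 of 29 alternatives (adjusted p = 0.00126 to 1 and 0.0139 to 0.712).

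The count of 2 genes called in input RNA became 1 with size factors, a total without ribosomal protein genes, no trend or only the groups compared. It also became 1 without both knockdown libraries numbered 3. With size factors the 1 gene was neither EIF3G nor THOP1 but EGR1, which was higher (2.41, adjusted p = 0.0228 by limma). With quantile normalization 1 gene was higher and 1 lower. The count became 24 with the axis term and 5 without the 3 libraries apart. It was 1 to 2 with any library or replicate number left out. In polysomal RNA the 2 genes became 1 with size factors, quantile normalization, no trend, only the groups compared, or without both knockdown libraries numbered 3. They became 10 with the axis term and 4 without the 3 libraries apart, and numbered 1 to 2 with libraries left out. For loading limma called 0 genes under each of the 31 alternatives.

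For polysomal against input RNA in control cells the 3912 genes became 1408 with a pseudocount of 5, 1249 with no filter, 610 with only the groups compared, 2121 with the replicate block, 650 with the axis term, 7960 without the 3 libraries apart and 2275 without both knockdown libraries numbered 3, and 5 to 7185 with libraries left out. In knockdown cells the 333 genes became 47 with size factors, 149 with no trend, 68 with only the groups compared, 75 with the replicate block within each siRNA, 1290 with the axis term and 7541 without the 3 libraries apart, and 8 to 788 with libraries left out. Without a replicate number fewer samples are fitted.

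With the axis term the 24 genes in input RNA became 15 with no filter, 12 with a minimum of 5 TPM, 65 with quantile normalization, 14 with the replicate block, 14 without the 3 libraries apart and 14 without both knockdown libraries numbered 3, and 3 to 597 with libraries left out. The 10 in polysomal RNA became 3 with a pseudocount of 5, 1 with no filter, 20 with size factors, 4 with quantile normalization, 5 with the replicate block and 3 without the 3 libraries apart, and 1 to 370 with libraries left out. The counts without replicate numbers 1, 2 and 3 were 597, 3 and 7 in input RNA.

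The Pearson correlation of the input and polysomal changes across genes, 0.399, reversed to -0.207 without siCtrl input 1, -0.0094 without siEIF3G input 3 and -0.241 without replicate number 1. It ranged from -0.241 to 0.79 with libraries left out and from 0.228 to 0.619 under the other alternatives.

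The number of lists called fell to 0 with an estimated correlation in all 5 comparisons, and to 0 with fry in 4 (1 in polysomal against input RNA of knockdown cells). Otherwise the 8 lists in input RNA ranged from 6 to 11 with libraries left out. The 7 in polysomal RNA became 11 with the axis term (5 to 12), the 7 in loading 14 without the 3 libraries apart (4 to 15), and the 4 in control cells 0 with a minimum of 5 TPM (2 to 5). The 7 in knockdown cells became 3 with quantile normalization, 4 without the 3 libraries apart and 4 without both knockdown libraries numbered 3 (5 to 8). For the list results, 574 of 689 alternatives kept the call and its direction and 115 lost the call. The median of ribosome biogenesis in input RNA, relative to all genes, turned to -0.076 (adjusted p = 0.0674) without replicate number 1.

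The cause of these changes was not tested, except that fewer samples or genes enter some of the fits. Same-number libraries correlated above 0.1 in 6 of 18 pairs (-0.689 to 0.712), by their deviations from the group means. Only the 6 pairs of the same siRNA could come from 1 lysate, and 3 of these were above 0.1. Whether the numbers pair libraries is thus not settled, and pairing was used only as the replicate block, over all libraries or within each siRNA. If the libraries are paired, the main fit ignores it. Leaving out a replicate number leaves 2 libraries in each group. Depth is unknown, since TPM carry no counts, so low values cannot be separated from counting error.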

Other observations

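Of the tests reported here, those of exchanged fraction labels, of mixed RNA and of the targets of ATF4 were chosen only after the result was seen, as was every value with the axis term.

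With the axis term, further genes moved in input RNA when adjusted over the list alone. JUNB, a transcription factor of the immediate early response, rose by 0.83 and DUSP1 by 0.70, and the chemokine CCL2 by 0.90 (SE 0.22, adjusted p = 0.00874). The histone genes H2AC6 (0.97), H2BC5 (0.72) and H2BC21 (0.50) rose and H4C3 (-0.92) fell. In polysomal RNA the chaperones HSPA5 (1.21), HSP90B1 (1.10, SE 0.25), CANX (1.04) and PDIA3 (0.99), which fold proteins in the endoplasmic reticulum, rose. The mitochondrial chaperone HSPD1 rose by 1.05 while its partner HSPE1 fell by 0.98. HSP90B1 alone passed in loading (1.31, SE 0.34, adjusted p = 0.0436 over its list). None of these genes passed over all genes.

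Genes of the amino acid response were high in both knockdown libraries numbered 3. TRIB3, a pseudokinase induced by ATF4, reached 352.91 TPM in input and 485.14 TPM in polysomal RNA, against 38.55 to 81.1 TPM in the other knockdown libraries. CHAC1, which degrades glutathione, reached 57.66 and 61.63 TPM against 5.83 to 8.25 TPM. Over the 33 tested targets the median excess over the other knockdown libraries was 1.64 in input and 1.32 in polysomal RNA, and 1.16 and 0.63 with the axis removed. The tables argue against the main axis between libraries, since this excess lay at percentile 100 of 10000 random lists in each fraction with the axis removed. They also argue against chance in a single library, since the excess in input and polysomal RNA correlated at r = 0.64 across these genes, which are not independent replicates. Activation of ATF4 in 1 culture from which both libraries came is a candidate explanation, and no biological explanation was tested, since the labels do not say which libraries share a culture.

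In 3 libraries, siCtrl input 1, siEIF3G input 2 and siEIF3G polysomal 3, the values lay nearer to the other fraction. Exchanged labels are argued against by MTRNR2L2, whose lowest input value was 95.7 times its highest polysomal value. Polysomal RNA mixed into the 2 input libraries would lower and raise genes by 1 share. In siCtrl input 1, however, the median share was 0.96 from the 3258 genes lower on polysomes and 0.043 from the 671 higher ones. In siEIF3G input 2 the shares were 0.877 and 0.18 (smaller difference 0.697). MTRNR2L2 alone gave 0.468 in siCtrl input 1 and 0.33 in siEIF3G input 2, between the 2 medians of each library. Input RNA mixed into siEIF3G polysomal 3 would bring MTRNR2L2, which stayed at 0.724% of its lowest input value. In this library the median share toward input was 0.648 from genes higher and 0.411 from genes lower on polysomes, so both sets moved toward input. The argument against mixing there rests on MTRNR2L2. The first axis held at least 67.8% of the variance within groups under other scalings. This share does not give the size of the variance left, so an effect of scaling to a fixed total stays open. RNA of lighter gradient fractions in siEIF3G polysomal 3, or a difference in RNA handling between libraries, stays open as untested, and no biological explanation was tested.

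The groups were also compared with other splits of the same samples. With 10 splits of 6 libraries the splits are too few for a share under 0.05, and only the counts are given. In input RNA 2 genes were called, 24 with the axis term, and 8 lists, against highest other values of 2183, 642 and 9, with 2 of the 10 splits as large each time. A split that called 2183 genes points to a structure of the samples, and it set siCtrl input 1 and siEIF3G input 2 and 3 against the other 3 libraries. In polysomal RNA 2 genes were called, 10 with the axis term, and 7 lists, against highest other values of 0, 1077 and 13, and 1, 2 and 6 of the 10 splits were as large. For polysomal against input RNA the 3912 genes in control cells and 333 in knockdown cells stood against 0 in the other splits (1 of 10 each). The 4 and 7 lists stood against 9 and 10 (6 and 3 of 10 splits). For loading limma called 0 genes in both fits, with 19 and 208 at an unadjusted p under 0.05. Any split reaches a count of 0 (100 of 100), so these splits test nothing for loading. That other splits called up to 2951 and 2811 genes points to the structure of the samples.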
